A study of Arabidopsis thaliana with 2 samples.

How the data were processed

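Total RNA of young leaves was hybridised to 2 dual-channel Agilent arrays, biological replicates 1 and 2 of the same design, with WT in Cy5 and 35S:NROB #2 in Cy3 per the labels. Per the labels' protocols, RNA was extracted with a column kit and labelled as amplified cRNA with a low-input dual-colour kit. Per the submitters' processing notes, Agilent Feature Extraction 8.5.1.1 was used. The deposited intensity values are normalised signals of each channel, per the file headers, and the method of normalization was not given in the sources used here. The deposited log2 ratio of each array is WT over NROB per the file headers, and it equalled the log2 ratio of the channel signals to within 9.6e-07 on every probe. The value table of the series equalled minus this ratio to within 5.0e-06, so it is the log2 ratio of 35S:NROB #2 over WT with no further centring. How the channel signals themselves were centred stays unknown. The deposited detection flags (another, non-numeric unit) give P, M or A once per probe and array, per the file headers. They pool the channels, since a probe given A had a signal of up to 13458 in one channel, and so could not show which channel was dim. Of 43603 probes, 26378 carried P on array 1, 25641 on array 2 and 25318 on both. A channel column of array 2 carries both names, WT and NROB, in its header, and was read as WT because the deposited ratio has it as numerator.

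All ratios were turned to 35S:NROB #2 over WT. Of 43663 features, 60 control spots were left out. Probes were named through a reference table of gene symbols and accessions: 34348 by accession, 1414 by locus, 714 by symbol, 21 by synonym, and 269 kept the name the array file gives, while 6837 stayed unnamed. This gave 26429 genes, 7845 with more than 1 probe. The array file's names can be old, and probes can bind near-identical paralogs, which these data cannot tell apart. Genome coordinates were not used here. Probes whose brighter channel mean fell under the 25th percentile of all probes, a signal of 12.9, were left out. That fallback was set before the data were examined for the case that no flag per channel was given. Probes of 1 gene were averaged, which left 20738 genes from 29363 probes. Of the 6487 genes with more than 1 probe here, 1502 had probes of opposite sign, and 4 of the 514 such genes over 2-fold.

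A channel was taken as above background where its probe was not given A or its signal exceeded the highest dimmer-channel signal of A probes, 50.1 on array 1 and 66.0 on array 2. Where a gene had 1 channel not above background on both arrays and the other above it on both, the change is given as "at least N-fold". This is the mean log2 signal of the bright channel against, per array, the higher of the dim signal and the lowest signal among P probes of that channel. These lowest signals were 28.0 and 25.4 for WT and 35.1 and 51.0 for 35S:NROB #2. They lie below the levels of 50.1 and 66.0, so "at least" holds against these floors only. Against the levels each bound would be smaller. The floors of WT are lower, so bounds of higher genes can come out larger than those of lower genes of equal brightness. No fold is given where neither channel was above background. Where a channel was above background on 1 array only, this is said beside the measured values, and its ratio on the other array stands against a background signal. Such bounds stay open to dye bias, as no dyes were swapped.

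The test of each gene was limma's lmFit and eBayes on the within-array log2 ratio against 0, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 1 residual degree of freedom, 2.28 prior degrees of freedom and a prior SD of 0.217. By sign flips alone, 2 arrays cannot give an exact two-sided p below 0.5, so each call rests on the spread shared across genes. Limma p-values measure the spread between these 2 arrays of 1 transgenic line. Those of camera, the list test described below, compare members with all other genes, taken as nearly independent. They therefore rest largely on the number of genes, and small values do not measure agreement of the 2 arrays. The threshold given with the series, a mean change over 2-fold, was counted as well, and so was a change over 2-fold on each array. The plus-minus values are SDs of the log2 ratios of the 2 arrays.

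Lists of genes were fixed before the data were examined and resolved through symbols. From them 6 symbols were removed because the reference gives that symbol to another gene (WIN1, CRT1, CAO, ORS1, SAUR21 and BAM3). Of 44 lists, 42 with at least 5 measured members were tested by camera with a preset correlation of 0.01, and the 2 lists of chloroplast-encoded and mitochondrion-encoded transcripts had no measured member. The tested lists held 1064 measured genes, 14 of them in more than 1 list, and 6 of the 12 touch and early wounding genes were also in another list. Named genes followed a fixed rule: the 12 higher and 12 lower genes over 2-fold on both arrays, ranked by the measured ratio of the weaker array whether or not a channel was near background, NROB itself where a feature carried its name, and in each list up to 4 members of the largest mean ratio. Any other gene is said to be chosen after its values were seen. A gene is said to have risen or fallen only where it passed limma over all genes.

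The method was tested on simulated data for the 20738 genes, with 200 changed genes in each of 10 runs. Genes changed by a log2 size of 1 were called in 0% of cases, of 2 in 3.28% and of 4 in 83.2%, and 4.67% of calls were unchanged genes. In 10 further runs a list of 25 members was shifted by 0.5, and it passed in 10 of 10 with the preset correlation and in 0 of 10 with an estimated one. Over the runs with and without this shift, 1 of 820 tests of other lists passed. Noise was drawn independently for each gene. These runs therefore cannot show how the preset correlation performs on lists whose genes move together. Alternatives changed the filter on dim probes, the source of the values, the scaling (centring, loess with a span of 0.3, quantile), the probes per gene, the variance prior, the pairing of channels, the thresholds, the set test and the replicates used. A further pair of filters, by detection flags and by channel detection, was chosen after seeing the data. Computation used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.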

Results

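Gene expression in young leaves of Arabidopsis thaliana was measured on 2 dual-channel Agilent oligonucleotide arrays. Each array held labelled RNA of wild-type (WT) plants of the Columbia-0 accession in the Cy5 channel and RNA of the transgenic line 35S:NROB #2, in the same background, in the Cy3 channel. The 35S promoter of cauliflower mosaic virus is widely used to express a gene strongly in most plant tissues. What NROB is was not given in the sources used here, 0 features carried that name, and the level of the transgene was not analysed here. Leaves came from plants of day 30, grown under 16 h of light at 22 °C and 8 h of dark at 20 °C, and the arrays were biological replicates 1 and 2. The median normalised signal was 149 for WT and 151 for 35S:NROB #2 on array 1, and 168 and 169 on array 2. The number of arrays, 2, limited the precision of every value.

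The comparison asked which genes differed in leaves of plants carrying the 35S:NROB transgene, the question named in the series title. Several genes of the pathogen response rose in leaves of 35S:NROB #2. FMO1 (AT1G19250), the monooxygenase that makes the systemic resistance signal N-hydroxypipecolic acid, rose at least 466-fold, with measured log2 ratios of 9.04 and 9.43 on the 2 arrays (limma adjusted p = 0.0379). This bound, like each bound below, holds against the floors of the dim channel only. Against the higher detection levels each would be smaller. PR1 (AT2G14610), the secreted protein used as the standard marker of salicylic acid responses, rose 87.0-fold (log2 6.44 ± 0.53, SD, n = 2, limma adjusted p = 0.0379). Fewer genes fell, among them CIPK25 (AT5G25110), a protein kinase bound by calcium sensors, which fell 9.70-fold (log2 −3.28 ± 0.36, SD, n = 2, limma adjusted p = 0.0455). NUDT24 (AT5G19470), a Nudix hydrolase, fell 10.8-fold on array 1 and at least 5.86-fold on array 2, where the transgenic channel was not above background (limma adjusted p = 0.0379).

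The 12 higher genes named for their rank were taken by measured ratio on both arrays, channels near background included, and FMO1 ranked first. AT3G13610, the feruloyl-CoA 6'-hydroxylase of scopoletin synthesis, rose at least 47.4-fold. GLIP1 (AT5G40990), a secreted lipase of fungal resistance, rose at least 51.1-fold. KTI1 (AT1G73260), a protease inhibitor of the Kunitz trypsin inhibitor type, rose at least 63.0-fold, and UPI (AT5G43580), another protease inhibitor, at least 63.6-fold. GLP9 (AT4G14630), a germin-like cell wall protein, rose at least 57.6-fold, the aspartyl protease family gene AT1G44130 at least 64.6-fold, and AT1G13520 at least 44.6-fold. For 3 genes WT was above background too. ARD3 (AT2G26400), an acireductone dioxygenase of methionine salvage, rose 254-fold (log2 7.99 ± 0.71, SD, n = 2). GSTU8 (AT3G09270), a glutathione transferase, rose 217-fold (log2 7.76 ± 0.66, SD, n = 2), and ABCG40 (AT1G15520), a plasma membrane transporter that takes up abscisic acid, rose 151-fold (log2 7.24 ± 0.71, SD, n = 2). The limma adjusted p of these genes lay between 0.0379 and 0.0491, and AT2G44240, at least 51.4-fold higher, missed the threshold at 0.0517.

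The 12 lower genes ranked first were taken by measured ratio as well. Where the transgenic channel was not above background the rank rests on that background signal, and the bound can be far smaller than the measured ratio. A wax gene passed, and 4 genes of anthocyanin synthesis or resembling it did not. WSD1 (AT5G37300), a wax ester synthase, fell at least 1.84-fold against a transgenic channel not above background (measured log2 −3.24 ± 0.15, SD, n = 2, limma adjusted p = 0.0379). PDF2.1 (AT2G02120), a defensin-like peptide gene, fell at least 1.39-fold, and AT1G70270 fell at least 4.09-fold (limma adjusted p = 0.0402 for both). The WT signals of PDF2.1, 52.1 and 66.3 on arrays 1 and 2, lay barely above the detection levels of 50.1 and 66.0. Against these levels the bounds of WSD1, PDF2.1 and AT1G70270 would be smaller, and that of PDF2.1 close to no change. AT4G15460 passed at 0.0455 but is given no fold, because WT was above background on 1 array only. The remaining 6 did not pass. COR15A (AT2G42540), which encodes a chloroplast protein protecting membranes in the cold, had log2 ratios of −2.74 and −4.23, 11.2-fold in the mean (adjusted p = 0.062). Anthocyanin genes had wider spreads between the arrays: DFR (AT5G42800), the dihydroflavonol reductase, at log2 −3.81 ± 1.69, and UF3GT (AT5G54060), which adds xylose to anthocyanins, at −4.00 ± 1.80 (adjusted p = 0.0818 and 0.0826). AT5MAT (AT3G29590), the malonyltransferase of the same pathway, was at least 4.42-fold lower (adjusted p = 0.055). AT4G22870, a dioxygenase gene next in number to the anthocyanidin synthase gene LDOX, stood at −3.93 ± 1.92, and GLC (AT1G65450), an acyltransferase-like gene, at −4.51 ± 1.99 (adjusted p = 0.0883 and 0.0809). The transgenic channel of DFR, UF3GT, AT4G22870 and GLC was above background on array 1 only, so their ratios on array 2 stand against background signals, with bounds there of at least 14.8-fold, 9.36-fold, 14.6-fold and 14.1-fold lower.

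In all, 155 of 20738 genes passed limma's test, 139 higher and 16 lower, so 89.7% were higher, and 6540 genes had an unadjusted p under 0.05. Each of the 155 was over 2-fold on both arrays. Of them, 134 had a probe with at least 1 channel detected on both arrays, and 41 had a probe given P on both. The share of higher calls depended on the scaling, with 282 higher and 77 lower after loess within each array (78.6% higher) and 375 higher and 99 lower after quantile normalization (79.1% higher). By the threshold given with the series, a mean change over 2-fold, 2838 genes differed, 1692 higher and 1146 lower. Of these, 896 had neither channel above background on either array, and 39 had opposite signs on the arrays. Over 2-fold in the same direction on both arrays were 1653 genes, 1165 higher and 488 lower. Across genes, which are not independent replicates, the log2 ratios of the arrays correlated with Pearson's r = 0.858 and Spearman's rho = 0.796. Ratios were wider on array 2, with an SD over genes of 1.06 against 0.741 on array 1. At an adjusted p under 0.05 the count of calls ranged from 0 with the brightest probe of each gene (6463 genes at an unadjusted p under 0.05, smallest adjusted p = 0.0523) to 2520 with the pairing of channels ignored, and at an adjusted p under 0.1 it was 3407. All WT samples carried Cy5, so a dye effect and the effect of the line cannot be separated.

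**Figure D1:**
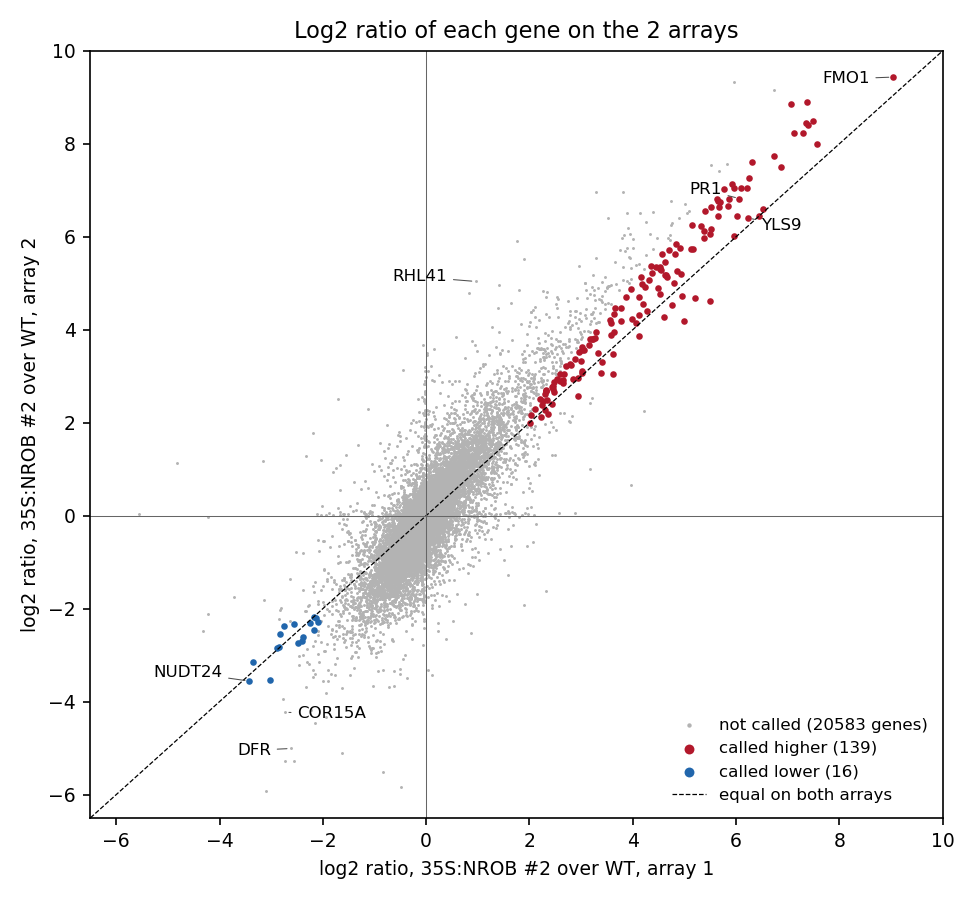
Each point is 1 gene, with its log2 ratio of 35S:NROB #2 over WT on array 1 (horizontal) and array 2 (vertical). Red and blue mark the 139 genes called higher and the 16 called lower, the dashed line marks equal ratios, and FMO1 lies at 9.04 and 9.43.

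**Figure D2:**
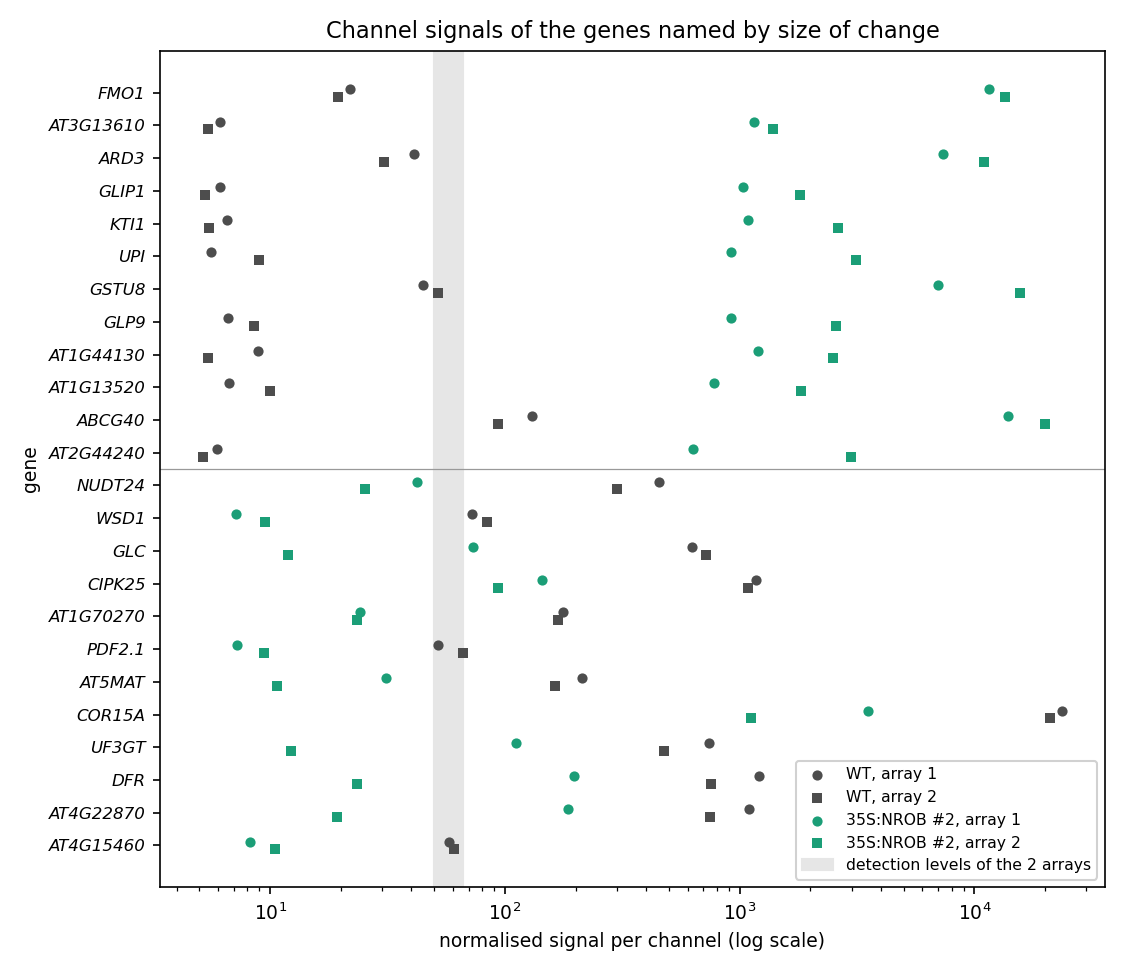
Normalised signal of each channel on a log axis for the 24 genes named by measured ratio, with WT in grey, 35S:NROB #2 in green, circles for array 1 and squares for array 2. The grey band spans the detection levels of the arrays, 50.1 and 66.0, and the WT signals of FMO1 lie left of it.

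Genes were then grouped by lists of pathways, cell types and hormone responses. Of 42 lists tested with camera, 18 passed, 7 higher and 11 lower, at the preset correlation of 0.01. With an estimated correlation 0 of the 42 passed and 0 had an unadjusted p under 0.05 (lowest adjusted p = 0.774). By fry, 0 passed and 4 had an unadjusted p under 0.05 (lowest adjusted p = 0.279). Under alternative filters, scalings and choices of probes at the preset correlation, 5 of the 18 lists missed the threshold at least once, and 9 of the other 24 passed at least once. With 1 residual degree of freedom the estimated correlation found a simulated shift of 0.5 in log2 in 0 of 10 runs. Larger list shifts were not simulated, so these runs cannot show whether it would miss those. The counts of members higher and lower on both arrays are given for each of the 18 lists. They are to be read against all genes in the fit, of which 37.6% were higher and 43.4% lower on both arrays. Counts of members adjusted over the list alone were not corrected for the 42 lists. They are not calls over all genes, and 6540 of all 20738 genes had an unadjusted limma p under 0.05.

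The salicylic acid and systemic resistance list rose, with all 25 measured members higher and 0 lower on both arrays. Its median log2 ratio was 2.25, 1.85 on array 1 and 2.59 on array 2 (camera adjusted p = 1.4e-14, adjusted p = 0.774 with an estimated correlation). Over all genes 4 passed higher, 0 lower and 21 not, and adjusted over the list alone 23 were higher and 0 lower. Beside FMO1 and PR1, these were ALD1, the aminotransferase of pipecolic acid synthesis, which rose 30.1-fold (log2 4.91 ± 0.38, SD, n = 2), and PRX52, a cell wall peroxidase, which rose 25.1-fold (log2 4.65 ± 0.18, SD, n = 2). Some members chosen after their values were seen show the rest of the pathway. EDS16, the isochorismate synthase that starts salicylic acid synthesis, stood at log2 2.00 ± 0.33, and PBS3, which conjugates isochorismate to glutamate, at 2.85 ± 0.36 (SD, n = 2). The regulators CBP60G and SARD1, which switch on EDS16, stood at 2.52 ± 0.63 and 2.09 ± 0.36, and BGL2, a pathogenesis-related glucanase, at 3.77 ± 0.79 (SD, n = 2). The receptor gene NPR1 lay at 0.20 ± 0.06 (SD, n = 2).

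The pattern-triggered immunity and camalexin list rose too, with a median log2 ratio of 1.73, 1.13 on array 1 and 2.65 on array 2 (camera adjusted p = 3.0e-07, adjusted p = 0.774 with an estimated correlation). Of 16 members 14 were higher and 0 lower on both arrays. Over all genes 4 passed higher, 0 lower and 12 not, and adjusted over the list alone 11 were higher and 0 lower. YLS9, a membrane protein induced by bacterial peptides, rose 79.9-fold (log2 6.32 ± 0.12, SD, n = 2). The camalexin pathway enzymes CYP71A13 and its close paralog CYP71A12 rose 43.1-fold (log2 5.43 ± 0.44, SD, n = 2) and at least 38-fold. PROPEP3, the precursor of a danger peptide and named because it passed, rose at least 7.66-fold. PAD3, the last enzyme of camalexin synthesis, had log2 ratios of 4.15 and 6.52 and did not pass (adjusted p = 0.0626).

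The unfolded protein response list rose, with all 11 members higher and 0 lower on both arrays and a median log2 ratio of 0.89, 0.75 on array 1 and 0.95 on array 2 (camera adjusted p = 1.1e-05, adjusted p = 0.774 with an estimated correlation). None of its 11 members passed over all genes, while 10 were higher and 0 lower adjusted over the list alone. TIN1, an endoplasmic reticulum stress gene, stood at log2 1.71 ± 0.38 and the chaperone gene BIP3 at 1.65 ± 0.64 (SD, n = 2). The other luminal chaperones BIP2 and BIP1 stood at 1.07 ± 0.21 and 1.05 ± 0.49 (SD, n = 2). The cytosolic ribosomal protein list rose by a smaller amount, a median log2 ratio of 0.46, 0.32 on array 1 and 0.59 on array 2 (camera adjusted p = 8.6e-14, adjusted p = 0.774 with an estimated correlation). Of its 304 measured members 252 were higher and 28 lower on both arrays, 0 passed over all genes, and 0 passed adjusted over the list alone. SAG24 and RPL3B, both genes of large-subunit proteins, stood at log2 1.45 ± 0.33 and 1.11 ± 0.32 (SD, n = 2).

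Lists of senescence, sugar starvation and ethylene also rose, with larger adjusted p, the last of them mainly on array 2. The senescence list had a median log2 ratio of 0.83, 0.69 on array 1 and 1.34 on array 2 (camera adjusted p = 0.0247, adjusted p = 0.774 with an estimated correlation). Of 17 members 11 were higher and 3 lower on both arrays. None passed over all genes, while adjusted over the list alone 9 were higher and 3 lower. The 3 lower were SAG29, PPH and ACD1. Chosen after their values were seen, PPH stood at log2 −0.86 ± 0.04 and ACD1 at −0.53 ± 0.08 (SD, n = 2). SAG12, the cysteine protease of late leaf senescence, was at least 12.4-fold higher (adjusted p = 0.0517), and SAG13, a dehydrogenase gene of early senescence, stood at log2 5.05 ± 1.61 (SD, n = 2, adjusted p = 0.0627). NAC042, a transcription factor that delays senescence, stood at 3.76 ± 0.57 (SD, n = 2, adjusted p = 0.0506). The sugar starvation list had a median of 0.72, 0.19 on array 1 and 0.96 on array 2 (camera adjusted p = 0.0247, adjusted p = 0.774 with an estimated correlation). Of its 15 members 10 were higher and 4 lower on both arrays, 1 passed higher and 0 lower, and adjusted over the list alone 6 were higher and 2 lower. DIN2, a beta-glucosidase induced in the dark, rose at least 25-fold, and ASN1, the dark-induced asparagine synthetase, stood at log2 2.05 ± 0.30 (SD, n = 2). SAG29, a sugar transporter gene in both lists, had log2 ratios of −2.22 and −4.19, with WT above background on 1 array and the transgenic channel on 0.

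The ethylene list had a median log2 ratio of 0.27, 0.09 on array 1 and 0.96 on array 2 (camera adjusted p = 0.0285, adjusted p = 0.774 with an estimated correlation). Of 21 members 10 were higher and 4 lower on both arrays, 1 passed higher and 0 lower, and adjusted over the list alone 5 were higher and 0 lower. In WT the median log2 difference of array 2 over array 1 was −0.35, against 0.23 over all genes. In the transgenic channel it was 0.17, against 0.21 over all genes. The higher median on array 2 thus lay mainly in lower WT signals there, as in the touch and early wounding list described below. ACS2, an enzyme making the ethylene precursor, rose at least 11.1-fold (limma adjusted p = 0.0379). The ethylene-responsive chitinase HCHIB stood at log2 2.45 ± 0.46, with probes between 0.59 and 3.43, and the response factor ERF1 at 1.67 ± 0.70 (SD, n = 2). With only probes called present on both arrays the list did not pass (adjusted p = 0.11, range over alternatives 0.015 to 0.774).

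Starch, cold and abscisic acid lists fell. All 18 starch members were lower and 0 higher on both arrays, with a median log2 ratio of −0.64, −0.50 on array 1 and −0.82 on array 2 (camera adjusted p = 1.1e-05, adjusted p = 0.774 with an estimated correlation). None passed over all genes, and adjusted over the list alone 0 were higher and 10 lower. BAM5 had the largest mean ratio, log2 −1.13 ± 0.79 (SD, n = 2). SEX4, a glucan phosphatase, and ISA3, a debranching enzyme, both of starch breakdown, stood at log2 −1.13 ± 0.20 and −0.98 ± 0.27 (SD, n = 2). RCP1, the chloroplast maltose exporter, stood at −0.87 ± 0.39 (SD, n = 2). The cold list had a median of −1.08, −0.99 on array 1 and −1.17 on array 2 (camera adjusted p = 7.1e-04, adjusted p = 0.774 with an estimated correlation). Of its 15 members 1 was higher and 11 lower on both arrays, 0 passed over all genes, and adjusted over the list alone 0 were higher and 10 lower. Beside COR15A, its neighbour COR15B stood at log2 −2.48 ± 1.00 and GolS3, a galactinol synthase, at −2.33 ± 0.78 (SD, n = 2). RHL41, a zinc-finger regulator also induced by wounding and oxidants, went the other way, with log2 ratios of 0.96 and 5.04. Its WT signal was 3357 on array 1 and 290 on array 2, and its signal in 35S:NROB #2 was 6544 and 9528. The abscisic acid and drought list had a median of −0.63, −0.39 on array 1 and −0.94 on array 2 (camera adjusted p = 0.0015, adjusted p = 0.774 with an estimated correlation). Of its 24 members 1 was higher and 14 lower on both arrays, 0 passed over all genes, and adjusted over the list alone 0 were higher and 1 lower. LTI78, a desiccation-induced gene, stood at −1.97 ± 0.41 and the proline synthesis gene P5CS1 at −1.68 ± 0.70 (SD, n = 2).

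Anthocyanin and surface lipid genes were lower as groups. The flavonoid and anthocyanin list fell, with a median log2 ratio of −1.16, −0.94 on array 1 and −1.32 on array 2, and −0.82 with members near background set to their bounds (camera adjusted p = 0.0247, adjusted p = 0.774 with an estimated correlation). Of its 21 members 5 were higher and 14 lower on both arrays, 0 passed over all genes, and adjusted over the list alone 4 were higher and 13 lower. TT4, the chalcone synthase that opens the pathway, stood at −3.01 ± 0.96 and LDOX, above background in the transgenic channel on 1 array, at −3.30 ± 1.63 (SD, n = 2). With only probes called present on both arrays the list did not pass (adjusted p = 0.304, range over alternatives 0.0109 to 0.774). The wax and cutin list fell, with a median of −0.43, −0.18 on array 1 and −0.79 on array 2 (camera adjusted p = 0.0037, adjusted p = 0.774 with an estimated correlation). Of 22 members 1 was higher and 15 lower on both arrays. WSD1 passed lower, 0 passed higher, and adjusted over the list alone 0 were higher and 3 lower. CER1, needed for wax alkanes, stood at −1.61 ± 0.78 (SD, n = 2), and CYP86A4, a fatty acid hydroxylase of cutin synthesis, was at least 1.74-fold lower (adjusted p = 0.0677).

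Markers of other cell types were tested in the same way, and those of guard cells and vascular tissue fell. The guard cell and stomatal lineage markers had a median log2 ratio of −0.80, −0.55 on array 1 and −0.95 on array 2, and −0.66 without the 2 members near background in both channels (camera adjusted p = 6.4e-05, adjusted p = 0.774 with an estimated correlation). Of 14 markers 13 were lower and 0 higher on both arrays, 0 passed over all genes, and adjusted over the list alone 0 were higher and 9 lower. TMM and SDD1, which space the stomata, stood at log2 −1.36 ± 0.47 and −1.68 ± 0.79, and OZS1, the anion channel of guard cells, at −1.32 ± 0.26 (SD, n = 2). The vascular markers had a median of −0.68, −0.46 on array 1 and −0.78 on array 2 (camera adjusted p = 0.0021, adjusted p = 0.774 with an estimated correlation). Of 13 markers 11 were lower and 0 higher on both arrays, 0 passed over all genes, and 0 passed adjusted over the list alone. IRX3, a cellulose synthase of xylem walls, stood at −1.08 ± 0.58, and the xylem protease genes XCP1 and XCP2 at −0.94 ± 0.67 and −0.82 ± 0.51 (SD, n = 2). These marker shifts moved with the starch, cold, wax, abscisic acid and anthocyanin groups, all lower in 35S:NROB #2.

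Trichome markers had a median of −0.54, −0.26 on array 1 and −0.69 on array 2 (adjusted p = 0.0634). Seed markers had a median of 0.69 (6 measured, adjusted p = 0.0638), but 5 of them had neither channel above background on either array, so it is a value of background signals. The detected one, FUS3, a regulator of seed maturation, stood at −1.06 ± 0.17 (SD, n = 2). With no filter on dim probes the seed median was −0.0039 (adjusted p = 0.626, range over alternatives 0.0638 to 0.774). Root markers (9 measured) had a median of −0.26, −0.12 on array 1 and −0.37 on array 2. Flower and pollen markers (6 measured) had one of −0.47, −0.11 on array 1 and −0.62 on array 2, and a mean of 0.13, of opposite sign. Both had adjusted p = 0.378, and 2 markers of each had neither channel above background on either array.

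Growth and photosynthesis lists fell by small amounts. The cell cycle and replication list had a median log2 ratio of −0.32, −0.20 on array 1 and −0.46 on array 2 (camera adjusted p = 0.0247, adjusted p = 0.774 with an estimated correlation). Of its 26 members 5 were higher and 16 lower on both arrays, 0 passed over all genes, and 0 passed adjusted over the list alone. CDKB1;2 had the largest mean log2 ratio of the list, −1.82 (limma adjusted p = 0.0805). It was 2.46-fold lower on array 1 and at least 1.95-fold on array 2, where the transgenic channel was not above background. SYP111, the syntaxin of the dividing cell plate, stood at −1.21 ± 0.43 and the mitotic cyclin CYCB1;3 at −1.11 ± 0.29 (SD, n = 2). With dimmer probes left out more strictly it did not pass (adjusted p = 0.0599, range over alternatives 0.0045 to 0.774). The leaf and shoot development list had a median of −0.31, −0.13 on array 1 and −0.43 on array 2 (camera adjusted p = 0.0247, adjusted p = 0.774 with an estimated correlation). Of its 24 members 3 were higher and 18 lower on both arrays, 0 passed over all genes, and 0 passed adjusted over the list alone. ANT, which prolongs organ growth, stood at −0.91 ± 0.36 and the growth factor gene GRF4 at −0.85 ± 0.32 (SD, n = 2).

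The Calvin cycle list had a median log2 ratio of −0.23, −0.19 on array 1 and −0.38 on array 2 (camera adjusted p = 0.0442, adjusted p = 0.774 with an estimated correlation). The photosystems and antenna list had one of −0.18, −0.05 on array 1 and −0.24 on array 2 (camera adjusted p = 0.0454, adjusted p = 0.774 with an estimated correlation). Of 16 Calvin cycle members 0 were higher and 11 lower on both arrays, and of 37 photosystem and antenna members 4 and 22. In both lists 0 passed over all genes, and 0 passed adjusted over the list alone. The bisphosphatase gene SBPASE stood at −0.54 ± 0.42 and PRK, the phosphoribulokinase, at −0.42 ± 0.07 (SD, n = 2). LHCB4.3, a minor antenna gene, stood at −0.98 ± 0.58, and NPQ4, needed to release excess light energy as heat, at −0.87 ± 0.20 (SD, n = 2). With the ratios centred on the median neither list passed (adjusted p = 0.0514 for both), nor with the brightest probe of each gene (adjusted p = 0.137 and 0.408). Over alternatives the adjusted p ran from 0.0082 to 0.774 for the Calvin cycle and from 0.0054 to 0.774 for the photosystems. Chlorophyll biosynthesis genes had a median of −0.01, but 0.23 on array 1 and −0.23 on array 2 (adjusted p = 0.868). Of its 13 members 2 were higher and 2 lower on both arrays.

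**Figure D3:**
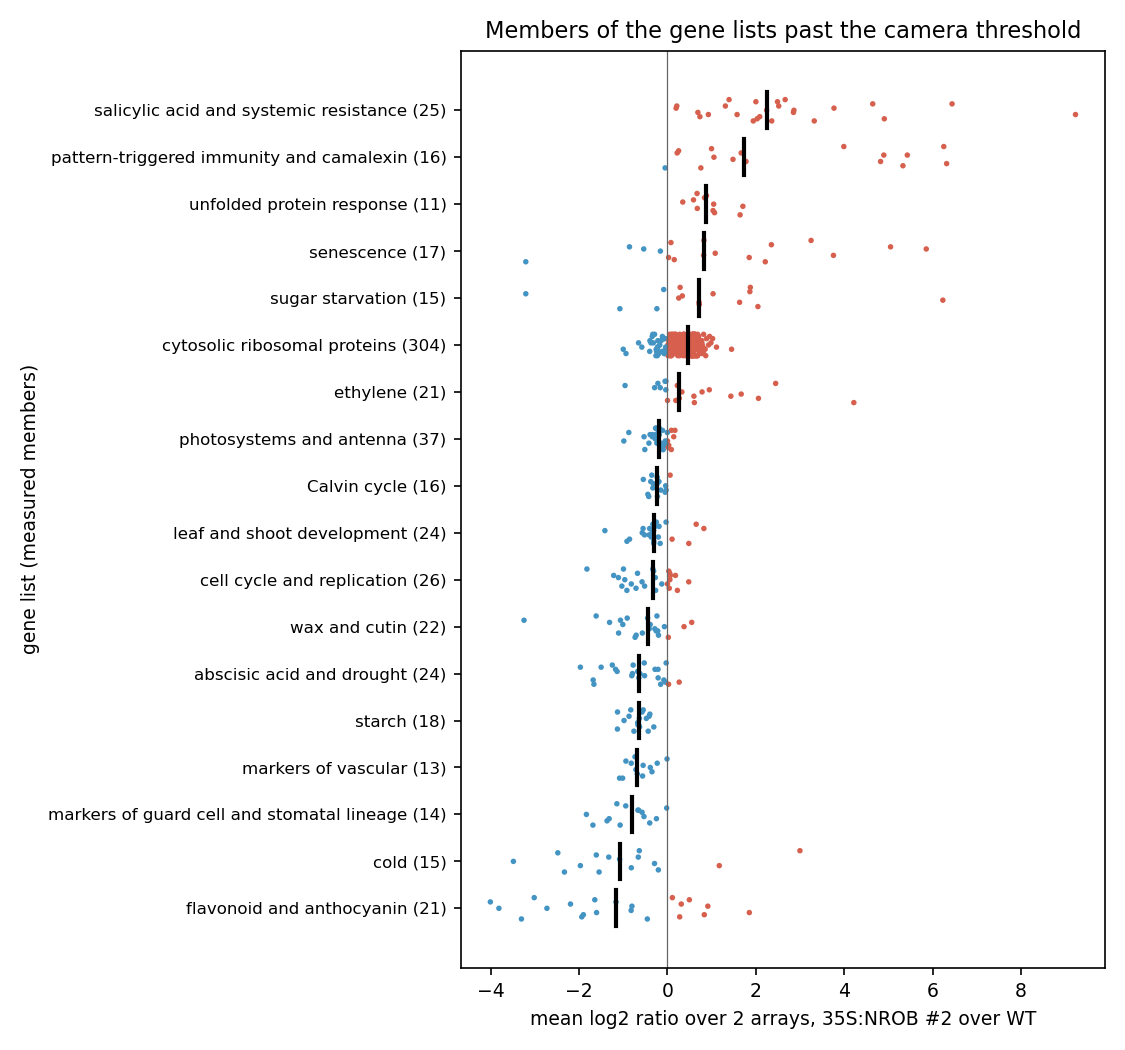
Each point is 1 measured member of the 18 gene lists that passed camera, at its mean log2 ratio of 35S:NROB #2 over WT on the 2 arrays, red above 0 and blue below. Black bars mark list medians, from 2.25 for salicylic acid and systemic resistance to −1.16 for flavonoid and anthocyanin genes.

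Among hormone lists that did not pass, medians lay between −0.20 and 0.15. The jasmonate list had a median of 0.09, but −0.24 on array 1 and 0.46 on array 2 (31 members, adjusted p = 0.855), with TAT3, a tyrosine aminotransferase, 9.16-fold higher in the mean (adjusted p = 0.0828), and CORI3, another aminotransferase-like wound gene, at log2 −1.76 ± 0.15 (SD, n = 2). The WT signals of 27 of the 31 members were lower on array 2 than on array 1, against 7 in 35S:NROB #2. The auxin list had a median of −0.18, −0.09 on array 1 and −0.19 on array 2 (adjusted p = 0.378). In it the auxin-conjugating enzyme gene GH3.3 stood at 1.62 ± 0.80 and AXR3, a repressor of auxin responses, at −1.19 ± 0.47 (SD, n = 2). BRU6 had the largest measured mean log2 ratio of the list, 2.78 (limma adjusted p = 0.0506), and DFL1 had one of 0.97 (limma adjusted p = 0.143). Gibberellin, cytokinin and brassinosteroid genes had medians of −0.20, 0.15 and −0.11 (adjusted p = 0.172, 0.252 and 0.455). On arrays 1 and 2 these were −0.14 and −0.35 for gibberellin, 0.21 and 0.17 for cytokinin, and −0.07 and −0.13 for brassinosteroid. ATGA2OX1, which inactivates gibberellins, was at least 3.17-fold lower (adjusted p = 0.0517). Among cytokinin genes CKX3, a cytokinin oxidase, had the largest measured ratio, higher in 35S:NROB #2, but with neither channel above background (adjusted p = 0.0511). ARR15, a cytokinin response regulator, was at least 2.22-fold lower (adjusted p = 0.0932).

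Stress and nutrient lists that did not pass held single genes with large ratios. In the oxidative stress list (median 0.11, 0.11 on array 1 and 0.22 on array 2, adjusted p = 0.0897) no member passed over all genes. In it the kinase gene AGC2-1 was at least 7.91-fold higher, and the glutathione transferase genes GSTF6 and GSTF7 stood at log2 3.12 ± 0.98 and 2.75 ± 0.44 (SD, n = 2), with adjusted p = 0.0641, 0.0633 and 0.0506. The touch and early wounding list had a median of 0.72, but −0.13 on array 1 and 1.33 on array 2 (adjusted p = 0.104). In it WRKY40, a repressor of defence genes, had log2 ratios of 0.44 and 2.90, and TCH3, a calmodulin-like protein gene, stood at 1.91 ± 0.71 (SD, n = 2). The WT signals of all 12 members were lower on array 2 than on array 1, with a median log2 difference of −1.88, against −0.23 in 35S:NROB #2 and 0.23 for WT over all genes. Heat shock genes had a median of 0.02, −0.12 on array 1 and 0.56 on array 2 (adjusted p = 0.378). The nitrate and nitrogen list had a median of 0.46, 0.26 on array 1 and 0.64 on array 2 (adjusted p = 0.0516). Of its nitrate transporter genes, NRT2.5 stood at 2.27 ± 1.82 with WT above background on 1 array, and NRT2:1 at −2.12 ± 0.94 with the transgenic channel above background on 1 array (SD, n = 2). LBD39, a nitrate-induced regulator, stood at 1.13 ± 0.63 and ASN1, also of this list, at 2.05 ± 0.30 (SD, n = 2). In the iron list (median −0.39, −0.24 on array 1 and −0.63 on array 2, adjusted p = 0.115) NAS1, a nicotianamine synthase, stood at −2.20 ± 0.21 (SD, n = 2, adjusted p = 0.0506), and the iron reductase gene FRO2 was at least 3.35-fold lower (adjusted p = 0.055). In the phosphate starvation list (median 0.21, 0.16 on array 1 and 0.28 on array 2, adjusted p = 0.231) SPX3, a phosphate-sensing gene, rose with the transgenic channel above background on 1 array and WT on 0, at limma adjusted p = 0.0455. BGLU28, a beta-glucosidase gene of the sulfur starvation list (median 0.09, −0.0040 on array 1 and 0.21 on array 2, adjusted p = 0.378), rose at least 2.66-fold (limma adjusted p = 0.0455). That bound holds against the floors of WT only. The transgenic signals of BGLU28 were 55.3 and 91.5 on arrays 1 and 2, where the detection levels were 50.1 and 66.0. Against these levels its bound would be smaller.

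The glucosinolate list had a median of −0.48, −0.39 on array 1 and −0.48 on array 2, and a mean of 0.07, of opposite sign (adjusted p = 0.153). In it MYB122, a regulator of indole glucosinolates, rose at least 20.4-fold (limma adjusted p = 0.0455). Its target CYP79B2, whose product feeds both indole glucosinolates and camalexin, stood at log2 1.91 ± 0.49 (SD, n = 2). The flowering time list had a median of −0.27, −0.18 on array 1 and −0.35 on array 2 (adjusted p = 0.0516), with CO, the photoperiod regulator, at −1.26 ± 0.13 and FT, the mobile flowering signal, at −1.96 ± 1.41 (SD, n = 2), both above background in the transgenic channel on 1 array. Circadian clock genes had a median of −0.12, −0.17 on array 1 and −0.07 on array 2 (adjusted p = 0.691). RVE8, a morning gene, had the largest measured ratio, higher in 35S:NROB #2, but with neither channel above background (adjusted p = 0.0794). ELF4, an evening gene, stood at −0.85 ± 0.01, and RVE2 and RVE1, related to RVE8, at 0.56 ± 0.53 and 0.49 ± 0.45 (SD, n = 2). Cell expansion and wall loosening genes had a median of −0.36, −0.13 on array 1 and −0.61 on array 2 (adjusted p = 0.0634), and XTH31, a xyloglucan-modifying enzyme gene, stood at −2.61 ± 1.01 (SD, n = 2). Aquaporin genes had a median of −0.35, −0.08 on array 1 and −0.62 on array 2 (adjusted p = 0.0638), with PIP2;8 at −1.34 ± 0.64 (SD, n = 2). Lignin and secondary wall genes had one of −0.82, −0.30 on array 1 and −1.15 on array 2 (adjusted p = 0.439), while OMT1, a methyltransferase of lignin precursors, stood at 1.25 ± 0.32 (SD, n = 2). The reference genes commonly used for normalization had a median of 0.03, 0.06 on array 1 and 0.03 on array 2 (15 genes, adjusted p = 0.455), with UBQ5 at 0.73 ± 0.29 and TUB6 at −0.51 ± 0.38 (SD, n = 2).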

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

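Probes with no gene name took no part in the comparisons above; the filter by channel detection used for them was chosen after seeing the data. They were looked at because a signal in them would otherwise go unreported. Of 1768 such probes with at least 1 channel detected on both arrays, 55 were over 2-fold higher in 35S:NROB #2 on both arrays and 26 over 2-fold lower. No WT-against-WT array was analysed here to give a background for these counts. Of 20738 named genes in the main fit, 1653 were over 2-fold in the same direction on both arrays, 1165 higher and 488 lower. Those are genes under another filter, and no excess among the unnamed probes is claimed. Which genes these probes measure was not given in the sources used here, and no explanation was tested.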

How the results depend on the processing

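Most alternatives were chosen before the data were examined; the filters by P flags on both arrays and by at least 1 channel detected were chosen after. The count of limma calls moved most. Against 155 it was 2363 with no filter on dim probes, 990 with ratios centred on the median, 359 after loess and 474 after quantile normalization, and all 155 calls were among the genes called under each. With each probe by itself 77 probes of 72 genes passed (66 of the 155 genes). The count was 0 with the brightest probe of each gene, 57 with a robust prior (all 57 among the 155), 2399 with an intensity trend, and 3407 at an adjusted p under 0.1. Filters also take called genes out of the test. With probes given P on both arrays 629 genes passed, where 41 of the 155 were tested and 40 passed. With at least 1 channel detected 444 passed, where 134 of the 155 were tested and 134 passed. With the stricter filter on dim probes 227 passed, where 98 of the 155 were tested and 97 passed. The channels of an array carry 1 replicate number, which the main test keeps as a pair; without that pairing, with no replicate block, 2520 genes passed. That fit had infinite prior degrees of freedom, against 2.28 in the main test, so all genes shared 1 variance in it. At an unadjusted p under 0.05 it had fewer genes, 4341 against 6540. Its higher count of calls therefore cannot be read as an effect of the pairing alone. Leaving out a replicate leaves limma no residual degree of freedom and so no test. The 2-fold count of 2838 lay between 2014 and 4195 without one replicate, and was 1332 with a stricter filter, 1286 with P on both arrays, 1797 with at least 1 channel detected, 5974 at 1.5-fold and 1166 at 3-fold; the filters test fewer genes. Over 2-fold on each array were 1653 genes, against 812, 719 and 1059 under those 3 filters and 3751 at 1.5-fold. The correlation of the arrays, 0.858, was 0.841 with no filter, 0.912 with the stricter filter, 0.845 per probe, 0.877 with P on both arrays, 0.904 with at least 1 channel detected, and 0.796 as Spearman's rho. Of the 18 lists that passed, 0 did with an estimated correlation and 0 by fry, and 13 passed under each filter, scaling and choice of probes tried. Of the 24 that did not pass, 9 did under at least 1 of these 10 alternatives: flowering time and aquaporins under 5 (lowest adjusted p = 0.0129 and 0.0200), cell expansion and touch under 3 (0.0241 and 0.0312), and trichome, iron, nitrate, oxidative stress and reference genes under 1 (0.0109, 0.0232, 5.8e-04, 0.0324 and 0.0198). With an estimated correlation each of the 9 had 0.774. Probes near background limited the rest: 896 of the 2838 genes had neither channel above it.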

Other observations

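The tests of gene families, of the spike-in slope and of the clock phases, and the division of the cell cycle list, were chosen only after related results were seen; the other tests were set before their result was seen. Families of genes sharing a symbol, 185 with at least 8 measured members, were tested like the lists, and 14 passed camera, 10 higher and 4 lower, but 0 with an estimated correlation (lowest adjusted p = 0.944). Probes of related genes can bind each other's transcripts. WRKY transcription factors, many of them regulators of defence, rose with a median log2 ratio of 1.05 over 57 genes, 0.74 on array 1 and 1.44 on array 2 (camera adjusted p = 7.9e-07, adjusted p = 0.944 with an estimated correlation). Of them 42 were higher and 7 lower on both arrays, 25 were over 2-fold higher on both, 0 passed limma over all genes in either direction, and the median of members outside the lists was 0.76. Cysteine-rich receptor-like kinases rose with a median of 1.16 over 32 genes, 26 of them higher and 4 lower on both arrays (camera adjusted p = 7.9e-07, adjusted p = 0.944 with an estimated correlation), and 1 member passed limma, CRK23 at 8.14-fold higher. Receptor-like proteins rose with a median of 1.01 over 49 genes, 34 of them higher and 12 lower on both arrays (camera adjusted p = 2.2e-05, adjusted p = 0.944 with an estimated correlation), and 1 member passed limma, RLP39 at least 5.48-fold higher. Glutamate receptor-like channels rose with a median of 1.18 over 17 genes, 10 of them higher and 4 lower on both arrays (camera adjusted p = 0.0288, adjusted p = 0.944 with an estimated correlation), or 0.65 without the 3 near background. Of its members 4 passed limma higher and 0 lower, among them GLR1.3 at least 32.6-fold and GLR2.9 at least 17.7-fold higher. The IRX family of secondary wall genes fell with a median of −0.83, all 10 lower and 0 higher on both arrays (camera adjusted p = 0.0107, adjusted p = 0.944 with an estimated correlation), and 0 passed limma over all genes. Of them 4 were in the lists, and the median of the others was −0.72. The lignin and secondary wall list itself did not pass (camera adjusted p = 0.439). Families with small shifts passed too. EIF had a median of 0.24 and UBQ one of 0.36 (camera adjusted p = 0.0194 and 0.0475, both 0.944 with an estimated correlation). The families described here were chosen after their values were seen. None of these medians changed sign under the scalings tried.

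Within the cell cycle list, mitotic and replication genes had different medians. The 13 mitotic cyclins, kinases and division genes had a median log2 ratio of −0.92, −0.62 on array 1 and −1.22 on array 2, and 12 were lower and 1 higher on both arrays. The 10 replication licensing and PCNA genes lay between −0.26 and 0.23, with a median of 0.05, 0.12 on array 1 and −0.03 on array 2. Of these 1 was lower and 4 higher on both arrays. The other 3 members, the D-type cyclins CYCD3;1, CYCD3;2 and CYCD3;3, stood at −0.71, −0.33 and −0.51. A two-sided permutation test over genes, with 100000 resamples, gave p = 0.005 for the difference between the groups of 13 and 10. It is void as evidence, because the groups were divided after their values were seen and genes are not independent replicates.

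Ratios were wider on array 2 than on array 1. Over 10 spike-in spots the slope of array 2 on array 1 was 1.012 (SE 0.0135), while the SDs of the genes stood in a ratio of 1.425, which argues against a difference in scale acting on every spot. Of 806 genes over 2-fold on array 1 with both channels detected, 85.1% had a larger ratio of the same sign on array 2 (median 2.07 against 1.41), which argues against noise of single genes on array 2. In the touch and early wounding list the difference lay mainly in WT, with signals lower on array 2 in all 12 genes. The jasmonate, ethylene and root marker lists resembled it. Their median log2 differences of array 2 over array 1 were −0.48, −0.35 and −0.48 in WT. In the transgenic channel they were 0.26, 0.17 and 0.19. Some lists that fell differed from it in this. For abscisic acid and drought the median log2 difference of array 2 over array 1 was 0.19 in WT and −0.48 in the transgenic channel. For flavonoid and anthocyanin genes it was 0.14 and −0.49, against 0.23 and 0.21 over all genes. The wider ratios thus cannot be placed in WT alone. No biological explanation was tested, and plants or leaves that differed between the replicates may stay as one.

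The defence lists, salicylic acid and pattern-triggered immunity together, were higher in a design where all transgenic samples carried Cy3. Among the 13 members with several probes the median of the lowest probe was 2.06, with 12 above 0 and the lowest at −0.12, which argues against a dye bias of single probes. The highest median among 10000 random lists matched on intensity was 0.25, against 2.09 for the 41 members, which argues against a dye bias that depends on intensity. The salicylic acid list still passed after loess within each array (adjusted p = 1.2e-13, range over alternatives 1.3e-20 to 0.774). A dye bias shared by probes of a gene, the genotype, the history of this 1 line and an infection of its plants stay open, untested.

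Starch, cold and abscisic acid genes vary with the time of day, and a harvest of the genotypes at different times is a candidate explanation for their lower levels. Morning-phased clock genes (7, median −0.03) minus evening-phased ones (8, median −0.19) gave 0.15, with a bootstrap SE of 0.277, and RVE8 among the morning-phased genes had neither channel above background. The smallest of the shifts of these lists was 0.632 in size, which lies less than 2 SE away, so the explanation cannot be told apart from an effect of the line with these few clock genes. An effect of the genotype on these groups stays open and was not tested.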
